A study of Mus musculus with 30 samples.

How the data were processed

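ATAC-seq libraries were made from nuclei of the ventral hippocampus of 30 mice, in a design of handling or chronic restraint by 0 min or 45 min after the start of acute restraint, with sex and batch (4 levels) in the labels. The deposited file gives raw counts, as whole numbers per peak region, for one set of regions common to all libraries. The authors' processing notes name Trimmomatic, Bowtie2, Picard, Genrich 0.6.1 and the genome build GRCm38. The notes do not state how the regions of the libraries were combined, which tool counted them, or whether reads, fragments or insertions were counted, so a count below is a count in a peak of unknown kind. The table held 2 further columns that matched no sample, and these were not used here. Libraries are named by their group and animal number.

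Peaks were annotated with a table of RefSeq genes on GRCm38 (21887 protein coding genes) by GenomicRanges 1.54.1 in R 4.3.3. Each peak took the name of its nearest gene, and any overlapping genes are named where they matter. The table gave gene extents without strand or exons, so transcription start sites, exons and introns were unknown, and peaks within 1 kb of either end of a gene stood in for promoter peaks. No genome sequence was used, so motif sets, planned as part of the list tests, and a correction for GC content were not run.

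Counts were analysed in edgeR 4.0.16. filterByExpr removed 6 of 257149 peaks and left 257143. Libraries were scaled by TMM, and a quasi-likelihood model (estimateDisp, glmQLFit with a robust trended prior) held the 4 groups, sex and batch. Tests were F-tests (glmQLFTest) with Benjamini-Hochberg adjustment over all tested peaks in a comparison, and a peak was called at an adjusted p under 0.05. The comparisons were the acute effect in each history and averaged over both, the effect of chronic restraint at each time and averaged over both, their interaction, and females against males. Differences of the acute and chronic effects between sexes came from a model of 8 cells of group and sex with batch. Sex was reported on autosomes, and the X and Y chromosomes served as a check of the sex labels by group means. Levels are TMM-scaled CPM (the count in a peak relative to the scaled library total) with the SD over libraries, and log2 changes carry the standard error of the fitted coefficient. P-values of single peaks measure the spread between animals. Those of camera rest also on the correlation taken between peaks, and Fisher's exact test treats peaks as independent units. The Wilson intervals of a share in a single library (95%) cover counting error only, since PCR copies are not independent molecules. Total counts of 26104576 to 55294838 gave a median peak a mean of 58.97 counts per library.

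The following choices were made before the data were examined: the tests, covariates and threshold, the gene lists, the rule for named peaks and the settings tried in place of the main ones, except where said otherwise. By that rule, each stress comparison and the sex comparison names the 12 called peaks with the smallest p in each direction, at most 1 per nearest gene, and where no peak passed the 3 with the smallest p. For 29 genes fixed in advance, the rule takes the gene-end peak with the highest mean count and the peak with the smallest p for the averaged acute effect, and those that matter to a group are printed. A peak named outside this rule is said to have been chosen after its values were seen.

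The 17 gene lists covered immediate early genes, glucocorticoid receptor targets, stress hormone and monoamine signalling, the circadian clock, glutamate receptors, GABA receptors, chromatin and DNA methylation enzymes, heat shock and chaperones, and markers of excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial and mural cells, choroid plexus and neighbouring brain regions. A peak belonged to a list if it lay within 10 kb of a list gene or within it. Lists were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 17 lists of a comparison, and again with an estimated correlation. Calls are also given adjusted over the list alone. Pairs of lists shared single genes: Dusp1 (immediate early genes and receptor targets), Per1 (receptor targets and clock), Gjb6 (receptor targets and astrocytes) and Drd1 (stress signalling and neighbouring regions). Most genes of the marker lists belong to cell types of the hippocampus itself.

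The peaks called for the averaged acute effect were tested as a set for a difference between histories with fry (limma), weighted by the sign of the effect, two-sided, and adjusted over the 4 comparisons tested on this set, or over both directions where batches were split. The ratio of the mean signed changes has a jackknife SE over 30 libraries, with the peaks held fixed. Quality measures of libraries were compared between times and between histories by two-sided permutation tests with 1e+05 resamples, adjusted over 8 tests. For the share of gene-end peaks Fisher's exact test was used.

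The model was tested on simulated counts with the design and spread of these libraries, in which 67 peaks were changed 1.25-fold, 67 were changed 1.5-fold and 66 were changed 2-fold among 257143. For the averaged acute effect it recovered 37.3%, 85.1% and 100% of them, for the acute effect in handled mice 14.9%, 58.2% and 95.5%, and in chronically restrained mice 11.9%, 55.2% and 97.0%. For chronic restraint it recovered 11.9%, 47.8% and 89.4% at 0 min, 16.4%, 46.3% and 90.9% at 45 min, and for the interaction 0%, 19.4% and 68.2%. Unchanged peaks made up 3.88% to 8.20% of the calls. The simulated counts held no batch or sex effects, and each peak was drawn on its own. Variation shared between peaks was thus absent, and these rates may be too favourable for the real libraries.

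The alternatives tried were DESeq2 size factors, total count scaling and loess offsets as normalization, no filter and a mean of at least 20 counts as filters, and the DESeq2 1.42.0 Wald test. Library pool in place of batch, no batch term, 2 surrogate variables (sva 3.50.0) and the share of counts in the most covered 1% of peaks changed the covariates. Each batch was left out in turn, each sex was analysed alone, sex chromosomes were left out, and the threshold was raised to 0.1. A fit without animal 45 was added after the data had been seen. Lists were also tested over gene-end peaks only, over 50 kb around genes and with total count scaling. To see how often other groupings call as many peaks, 40 splits of the libraries, the real one included, were fitted with the dispersion trend of the reported model. Times were shuffled within histories, histories within times and sexes within groups. The closing section gives the effect of these settings.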

Results

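The study asked how a history of repeated stress alters the response of the ventral hippocampus to a later acute stress. Open chromatin was measured by ATAC-seq, in which a transposase cuts accessible DNA and the cut fragments are sequenced, in nuclei of the ventral hippocampus of 30 mice. Mice were either handled or restrained in a tube daily for 10 days. After 24 hours of single housing they were collected from the home cage (0 min) or 45 min after the start of an acute restraint. The groups held 8 handled mice at 0 min, 7 handled mice at 45 min, 8 chronically restrained mice at 0 min and 7 chronically restrained mice at 45 min. Each group held both sexes, with 4 females and 4 males at 0 min in both histories, 3 females and 4 males among the handled mice at 45 min, and 4 females and 3 males among the chronically restrained mice at 45 min. The libraries came from 4 batches, and each batch held all 4 groups. Each library was the tissue of a separate animal. The count table gave 257149 peak regions, and the total count in peaks ran from 26104576 to 55294838 per library. The median peak was 561 bp wide and had a mean of 58.97 counts per library. Peaks were named by the nearest gene, which need not be the gene a peak acts on.

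As groups, the sex labels matched the sex chromosomes, with 82 of 2026 X chromosome peaks more accessible in females and 4 of 28 Y chromosome peaks less accessible in females (edgeR, adjusted p under 0.05). This compares group means and does not check the label of each animal. Total count, the share of counts within 1 kb of a gene end, the share in the most covered 1% of peaks and the share of empty peaks did not differ between times or histories by permutation test (smallest unadjusted p = 0.427, adjusted p = 0.972). The library of animal 45, a handled female at 0 min, stood apart from its group. It had 42.1% of its counts at gene ends (95% Wilson interval 42.13 to 42.16), against 37.7% to 39.6% in the other 7 libraries of its group. Counts of called peaks without it are given below where they moved by over 1.5 times, and those for chronic restraint at 0 min, at 45 min and averaged, and for the interaction, were 0 with and without it.

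Accessibility was higher 45 min after the start of acute restraint near several genes known as targets of the glucocorticoid receptor. This is the nuclear receptor for the stress hormone corticosterone. Averaged over both histories (14 libraries at 45 min, 16 at 0 min), accessibility rose within Fam107a, which encodes an actin-binding protein induced by glucocorticoids, by a log2 change of 0.40 ± 0.048 (SE). It rose by 0.51 ± 0.068 beside Sgk1, the serum- and glucocorticoid-regulated kinase, and by 0.27 ± 0.035 over Plin4, a lipid droplet coat protein. The smallest p belonged to a peak near Ttyh1, which encodes a membrane protein of the tweety family, with a log2 change of 0.84 ± 0.097. Other peaks that rose lay within Kcnk2, a leak potassium channel (0.44), within Adamts9, an extracellular metalloprotease (0.51), and within Washc2, a part of the WASH complex of endosomes (0.64).

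At the Ttyh1 peak (GRCm38, chromosome 7, 4111520 to 4112134, between genes and 7396 bp from the nearest gene end) the mean CPM (count relative to the scaled library total) was 1.64 ± 0.46 (SD, n = 8) in handled mice at 0 min and 2.86 ± 0.55 (n = 7) at 45 min. In chronically restrained mice it was 1.35 ± 0.37 (n = 8) and 2.53 ± 0.39 (n = 7). The Fam107a peak (chromosome 14, 8308240 to 8311789, within the gene) went from 13.9 ± 1.1 to 18.04 ± 1.2 CPM in handled mice and from 14.03 ± 2.1 to 18.9 ± 1.4 CPM in chronically restrained mice. The Sgk1 peak (chromosome 10, 21999952 to 22001215) lay 49 bp from an end of that gene, and the Plin4 peak (chromosome 17, 56095359 to 56117927) was 22569 bp wide and also covered Hdgfl2 and Plin5. The adjusted p was 1.5e-07 for Ttyh1, 2.1e-07 for Fam107a, 2.4e-06 for Plin4 and 6.7e-06 for Sgk1 (edgeR). Peaks whose nearest genes were Usp24 (0.88), Actl7b (0.91), Cdc37l1 (0.53), Gm4791 (0.52) and Phyhd1 (0.30, overlapping Lrrc8a) completed the 12 named peaks that rose. The largest adjusted p among these 12 was 9.7e-06.

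**Figure D1:**
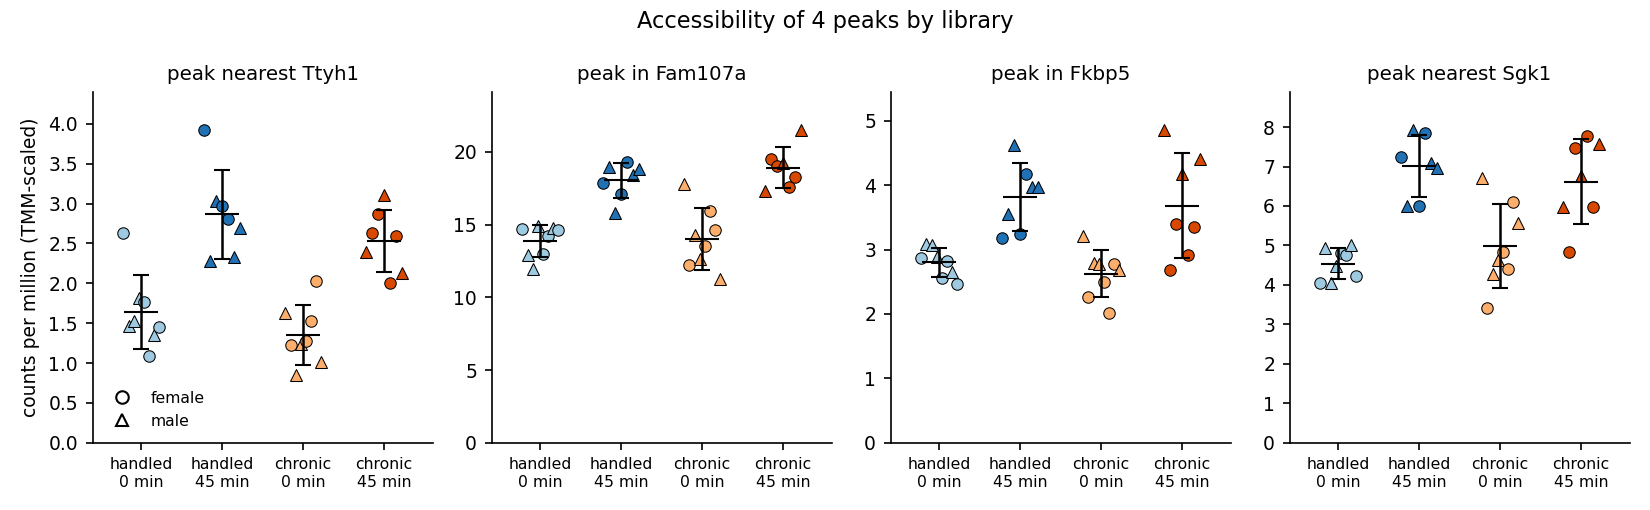
TMM-scaled CPM (vertical axes from 0) at the peaks near Ttyh1, in Fam107a, in Fkbp5 and near Sgk1 for each of the 30 libraries by group; circles are females, triangles males, and bars give the mean and SD. At the Sgk1 peak the handled mice at 0 min lie between 4.04 and 5.01 CPM and the handled mice at 45 min between 6.01 and 7.94 CPM.

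Fewer peaks fell than rose at 45 min, a balance that turned with the share of counts in the most covered 1% of peaks as a covariate (498 rose and 1265 fell). The peak with the smallest p among those that fell lay within Pcdh15, a protocadherin (chromosome 10, 74403203 to 74403534, log2 change −0.73 ± 0.12, adjusted p = 1.3e-04). Its mean CPM was 1.47 ± 0.41 and 0.906 ± 0.26 in handled mice at 0 and 45 min, and 1.34 ± 0.15 and 0.772 ± 0.15 in chronically restrained mice. Accessibility also fell within Hdac9, a class IIa histone deacetylase (−0.50), within Prkar2a, a regulatory subunit of protein kinase A (−0.49), within Ano10 (−0.53) and Nrep (−0.33), and 93367 bp from Adcyap1, the gene of the neuropeptide PACAP (−0.58). The other named peaks that fell were nearest to Trabd2b (−0.42), Naf1 (−0.52), Septin7 (−0.61), Pdcd6ip (−0.47), Ppp2r2b (−0.40) and Gm52030 (−0.39).

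In all, 299 of 257143 tested peaks passed an adjusted p of 0.05, of which 188 rose and 111 fell, with a median absolute log2 change of 0.37. All 111 peaks that fell and 187 of the 188 that rose had the same sign in each of the 4 batches, on which they were also selected. Of the peaks that rose, 14.4% lay within 1 kb of a gene end, against 1.8% of those that fell and 10.4% of all tested peaks (27 against 2 peaks, odds ratio 9.09, Fisher's exact test, two-sided p = 1.8e-04). The peaks that rose were also wider (median 1182 against 674 bp) and more covered (median of 181 against 87.6 mean counts). The comparison was not adjusted for this, and it treats peaks as independent, so its p does not measure the spread between animals. Tested within single batches, the counts were 0, 141, 12 and 7. The count was 681 without animal 45 (485 rose), 40 without batch 2, 20 in females and 105 in males, and other settings that moved it by over 1.5 times are given in the closing section.

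The glucocorticoid receptor targets were the list with the clearest movement among 17 gene lists fixed before the data were examined. Of the 426 peaks within 10 kb of its 30 genes, 19 rose and none fell, at 12 genes. These included Fkbp5, a co-chaperone of the glucocorticoid receptor, Zbtb16, a zinc finger transcription factor, Klf15 and Hif3a, transcription factors, Nfkbia, an inhibitor of NF-kappaB, and the metallothionein genes Mt1 and Mt2. Adjusted over the list alone, 64 peaks rose and 2 fell, both near Sesn1. The list's median log2 change was 0.084, 77.5% of its peaks had a positive change, and camera gave an adjusted p of 1.6e-20, or an adjusted p of 6.5e-07 with an estimated correlation. The mean change of the list was 0.048, 0.10, 0.084 and 0.12 in batches 1 to 4, and the number of its peaks that rose was 5 without batch 2, 8 without batch 3, 5 in females, 7 in males and 33 without animal 45.

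Within the list, the share of peaks with a positive change differed between genes. All 32 peaks within 10 kb of Fkbp5 had a positive change, with a median of 0.24, and 4 passed. All 20 peaks of Hif3a and all 11 of Klf15 were also positive, with medians of 0.13 and 0.15, and 2 and 1 of them passed. Of the 70 peaks of Zbtb16 92.9% were positive and 3 passed. At Sgk1, by contrast, 53.3% of 45 peaks were positive, with a median of 0.016, and 1 passed, or 4 when adjusted over the list alone. These shares were not tested gene by gene. The peaks of Tsc22d3, Per1, Ddit4 and Dusp1, also glucocorticoid-responsive genes, gave no call, with a smallest-p log2 change of 0.091 ± 0.056 at Tsc22d3, 0.17 ± 0.11 at Per1 and 0.094 ± 0.035 at Ddit4.

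**Figure D2:**
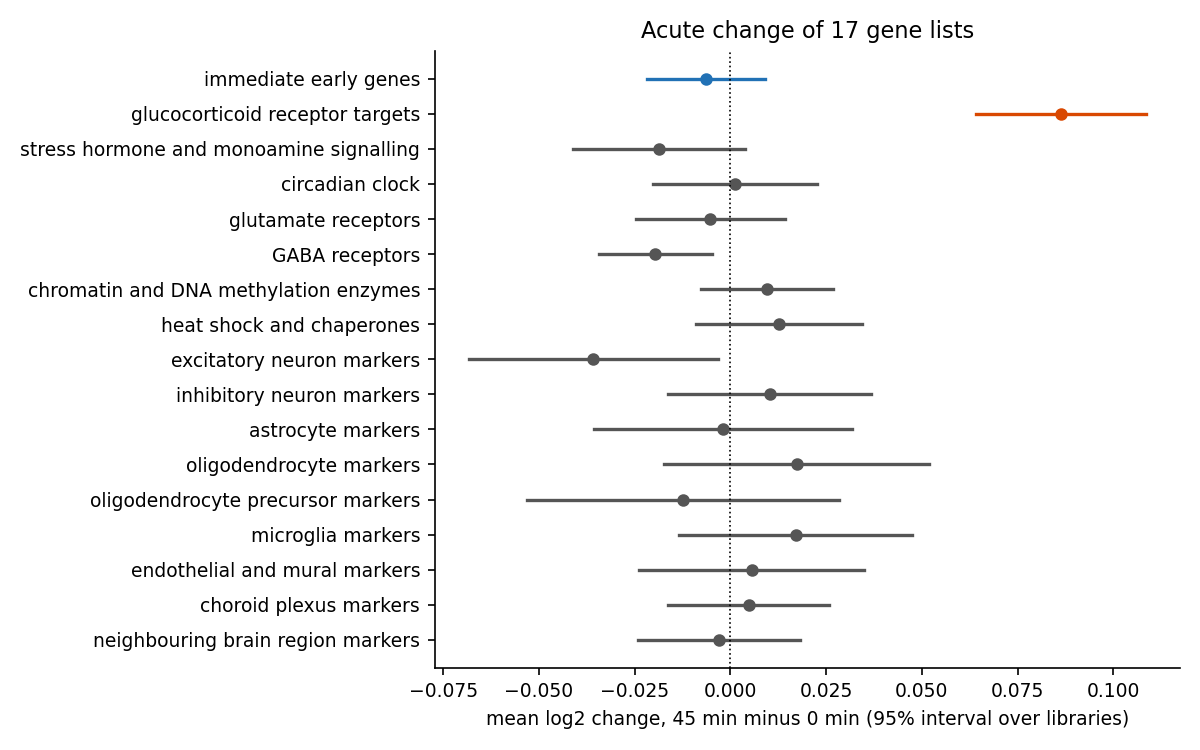
Mean log2 change in accessibility at 45 min against 0 min, averaged over both histories, for the peaks of 17 gene lists; points are the mean over a list's peaks and lines its 95% interval over the 30 libraries, adjusted for sex and batch. The glucocorticoid receptor targets lie at 0.086 (0.064 to 0.11) and the immediate early genes at −0.0065 (−0.022 to 0.0089). The intervals of GABA receptors (−0.034 to −0.0049) and excitatory neuron markers (−0.068 to −0.0034) also exclude 0, without a camera call.

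At Fkbp5 and between it and its neighbour Armc12, 6 peaks rose. In a window from 10 kb before Fkbp5 to 10 kb past Armc12 on chromosome 17, all 41 peaks had a positive acute change, with a median of 0.23, and the other 35 did not pass. The smallest change was 0.010 ± 0.099, and no test of the region as a whole was made. The largest change was 0.46 ± 0.072 within Fkbp5 (28420165 to 28421347, adjusted p = 1.0e-04). Here the mean CPM went from 2.80 ± 0.23 to 3.82 ± 0.52 in handled mice and from 2.63 ± 0.37 to 3.68 ± 0.81 in chronically restrained mice. A peak of 14182 bp between Fkbp5 and Armc12 (28515115 to 28529296) rose by 0.23 ± 0.036 (adjusted p = 8.7e-05). The window was chosen after the values of these peaks were seen.

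**Figure D3:**
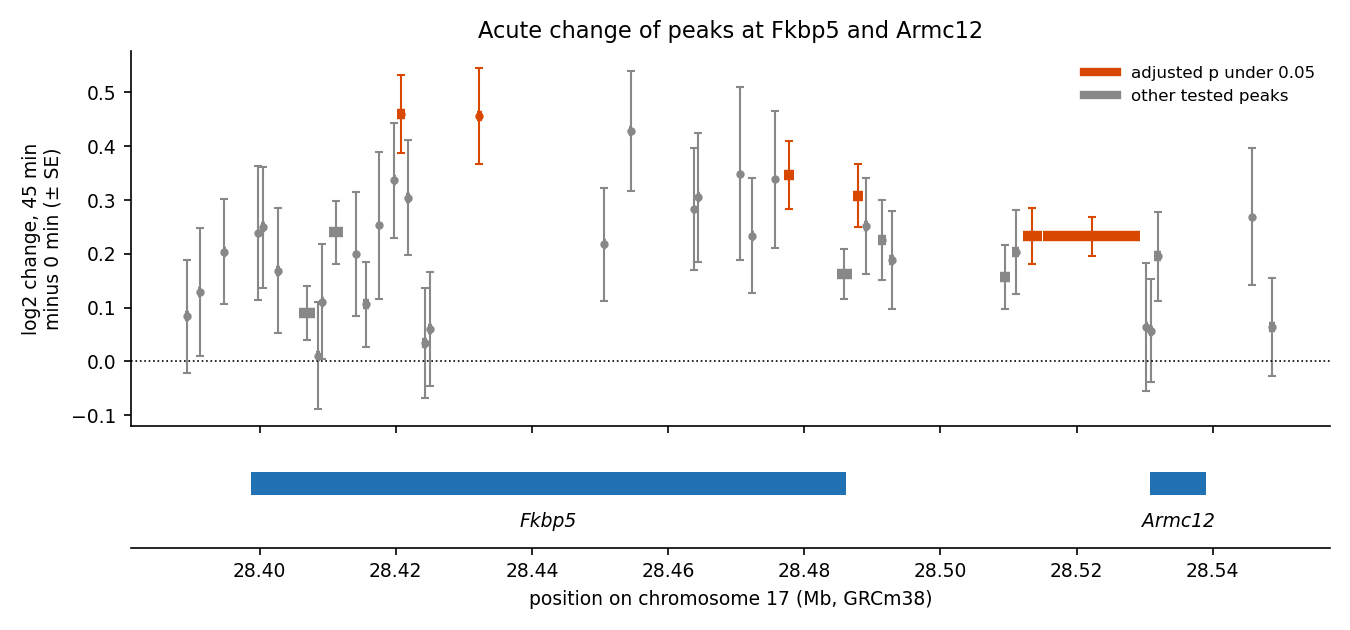
Acute log2 change (45 min minus 0 min, averaged over both histories) of the 41 tested peaks around Fkbp5 and Armc12 on chromosome 17 (GRCm38, Mb); thick lines span each peak, thin lines give ± SE, and the lower track shows the extent of both genes. All 41 values lie above 0, and the 6 peaks with an adjusted p under 0.05 lie between 0.23 and 0.46.

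The immediate early genes, whose transcription rises within minutes of neuronal activity, did not gain accessibility as a group. None of the 434 peaks of 47 genes passed (edgeR over all peaks), 2 fell when adjusted over the list alone, at Npas4 and Pcsk1, and the median change was −0.0054 (camera adjusted p = 0.786, and 0.816 with an estimated correlation). At Npas4, an activity-dependent transcription factor, the peak with the smallest p had a log2 change of −0.19 ± 0.046 (adjusted p = 0.0780), with 18.02 ± 1.9 and 15.4 ± 1.7 CPM in handled mice at 0 and 45 min. The wide peak over Fos had a change of −0.097 ± 0.041 (adjusted p = 0.567), and the smallest-p peaks of Arc, Egr1, Nr4a1 and Bdnf had changes of −0.026, −0.094, −0.080 and −0.12, none of which passed. Members of the list lay on both sides of 0, and 19 of the 47 genes had a positive median over their peaks, among them Sik1 (0.13, 12 of 12 peaks positive), Klf2 (0.098) and Atf3 (0.087), chosen after their values were seen. By batch the mean change of the list was −0.0032, 0.0020, −0.023 and 0.00010.

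No other list passed camera for the averaged acute effect. Single peaks were called within some of them. Rora, a nuclear receptor of the clock list, and Adarb2, an interneuron marker, each had a peak that rose, as did Mobp of the oligodendrocyte list. Hdac9 of the chromatin list and Slc4a4, an astrocyte bicarbonate transporter, each had a peak that fell. Among markers of cell types, the median log2 change was −0.024 for excitatory neurons (camera adjusted p = 0.444), 0.016 for inhibitory neurons (0.484), 0.0082 for astrocytes (0.909), 0.0077 for oligodendrocytes (0.444), 0.00094 for their precursors (0.797), 0.011 for microglia (0.484) and 0.0044 for endothelial and mural cells (0.786). For choroid plexus markers it was −0.014 (0.786), and for markers of neighbouring brain regions 0.0018 (0.909). The lists of stress hormone and monoamine signalling (−0.021, 0.524), the circadian clock (−0.0055, 0.909), glutamate receptors (−0.00023, 0.947), GABA receptors (−0.010, 0.676), chromatin and DNA methylation enzymes (0.0096, 0.524), and heat shock and chaperones (0.011, 0.524) completed the 17. The mean, as plotted, and the median differed in sign for the clock list and for astrocyte, precursor, choroid plexus and neighbouring region markers, and the direction of the test differed from the median for the clock, precursor and choroid plexus lists. Adjusted over the list alone, oligodendrocyte peaks went both ways, with 7 higher at Mbp and Mobp and 2 lower at Ermn and Sox10. At the receptor and cofactor genes of the stress axis, the smallest-p peaks of Nr3c1, which encodes the glucocorticoid receptor, Crhr1 and Crhbp had changes of −0.24 ± 0.092, −0.074 ± 0.049 and −0.30 ± 0.11, and none passed.

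In handled mice, for which the acute restraint was the first, the acute response rose most clearly at Sgk1 (0.62 ± 0.096), Irak2, a kinase of interleukin receptor signalling (0.78 ± 0.13), Gatb, a mitochondrial amidotransferase subunit (0.45 ± 0.073), and Ttyh1 (0.82 ± 0.13). A peak within Rora rose by 0.99 ± 0.17. Peaks near Plin4 (0.29), Washc2 (0.74), Cdc37l1 (0.59), Phyhd1 (0.34), Dnajc27 (0.49) and Fam107a (0.38) also rose, as did a peak 51507 bp from Ampd3 (0.48). Peaks within Prkar2a (−0.66), Mia2 (−0.79) and Cdk19, a kinase of the Mediator complex (−0.73), fell. Of the glucocorticoid receptor target peaks 4 rose, at Fam107a, Klf15, Plin4 and Sgk1, and 24 rose and 1 fell when adjusted over the list alone (median 0.076, camera adjusted p = 5.2e-12, adjusted p = 4.7e-05 with an estimated correlation). No other list passed. In all 28 peaks passed with 7 mice at 45 min against 8 at 0 min, of which 25 rose and 3 fell, and the smallest adjusted p was 0.0024 (edgeR). With the top-peak share as a covariate the balance turned (375 calls, 92 higher and 283 lower), total count scaling gave 64 calls with 76.6% rising, against 89.3% of the 28, and the count was 108 without animal 45, 0 without batch 2, 0 without batch 3, 0 in females and 0 in males. Tested within batches 1, 2 and 3 alone, the counts were 2, 13 and 17, and the 17 in batch 3 all fell. Batch 4 held a single handled library at 45 min, so its count is not read.

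In chronically restrained mice the acute response was again a gain, at 7 peaks and with none falling. Accessibility rose near Fam107a (0.43 ± 0.068), Ttyh1 (0.86 ± 0.14) and Kcnk2 (0.45 ± 0.083), which were also called in handled mice. It also rose near Parg, the glycohydrolase that removes poly(ADP-ribose) (0.55). Further peaks rose far from their nearest gene: 115840 bp from Usp24, a deubiquitinase (0.99 ± 0.16), 88648 bp from Gm4791 (0.59) and 85308 bp from Actl7b (1.04 ± 0.18). A single glucocorticoid receptor target peak passed over all peaks, at Fam107a, and 27 rose and 0 fell when adjusted over the list alone (median 0.088, camera adjusted p = 2.4e-13, adjusted p = 2.1e-05 with an estimated correlation). No other list passed. The smallest adjusted p was 0.0025 (edgeR, 7 mice at 45 min and 8 at 0 min). The count was 47 without animal 45, which belongs to the other history but shares the model, 0 without batch 2, 1 without batch 3 and 0 in females. Within single batches the counts were 0, 22 (11 higher and 11 lower), 0 and 26 (25 higher and 1 lower), the last with 1 library at 45 min, and the top-peak share as a covariate gave 41 higher and 14 lower.

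The responses of both histories were compared at 3 levels, and no difference passed. No single peak passed the interaction test (edgeR and DESeq2, 0 calls each; 7796 peaks had an unadjusted p under 0.05, against 12857 expected by chance; smallest adjusted p = 1). Within single batches the counts were 9, 11, 1 and 15, with the 11 in batch 2 negative and the others positive. Batch 4 held 1 library of each history at 45 min, of opposite sex, so its 15 calls do not separate history from sex or animal. The named peaks with the smallest p were near Scmh1 (−1.33 ± 0.31), within Shtn1, an axon guidance protein (−1.07 ± 0.27), and near Mcm9 (0.75 ± 0.19). Of the 32 peaks called in either history all changed in the same direction in both, with a Pearson r of 0.80 across these selected peaks and 0.17 across all tested peaks, which are not independent replicates. The 2 lists shared 3 peaks, against 0.00076 for independent lists in which every tested peak is equally likely to be called. Both lists came from 1 fit with a shared estimate of each peak's spread. The same peaks can thus be favoured in both, and this contrast overstates the agreement. The difference had an unadjusted p under 0.05 at 5 of the 32 peaks, within or near Cdk19, Nkd2, Gatb, Irak2 and Rora, and the smallest p adjusted over these 32 was 0.0625. All 5 were called in handled mice alone, a choice that enlarges the handled change and with it the difference. Nkd2 was chosen after its values were seen. The gain at Nkd2 was 0.85 ± 0.16 in handled and 0.19 ± 0.15 in chronically restrained mice.

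**Figure D4:**
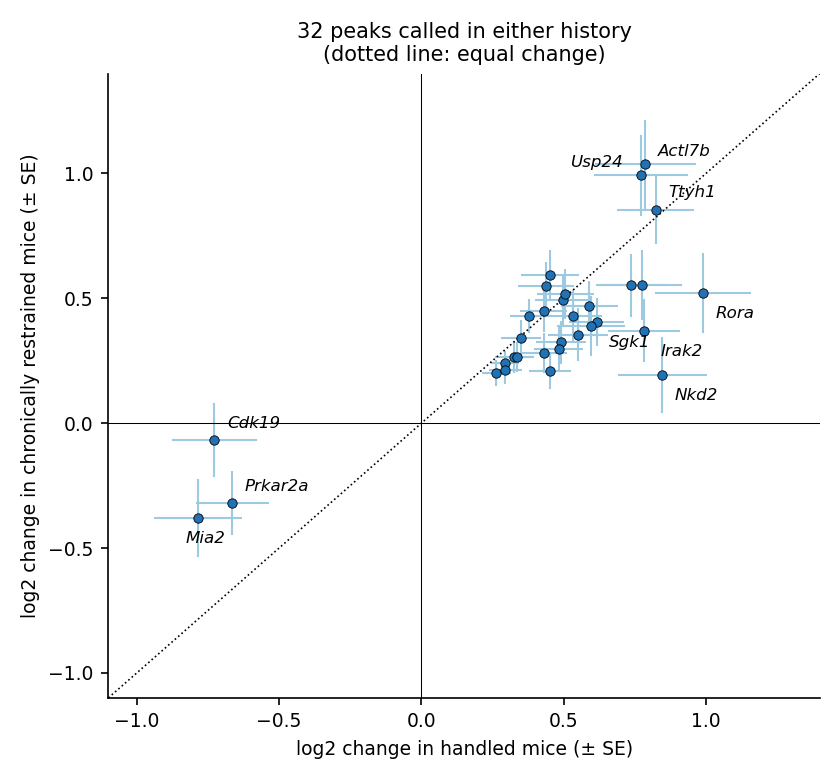
Acute log2 change (45 min minus 0 min) in handled mice (horizontal) and chronically restrained mice (vertical) at the 32 peaks called in either history; lines give ± SE, the dotted line marks an equal change, and some peaks carry the name of their nearest gene. All 32 peaks lie in the same direction in both histories, with Cdk19 at −0.73 and −0.068 and Actl7b at 0.79 and 1.04.

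No difference in the response of the 299 acute peaks was detected when they were tested as a set. The mean signed log2 change was 0.41 in handled and 0.39 in chronically restrained mice. The ratio of chronically restrained to handled was 0.950 ± 0.085 (jackknife SE over 30 libraries, 95% interval 0.784 to 1.12), and the fry test of the difference gave an adjusted p of 0.871 over 4 tests of this set. Leaving out each library in turn kept the ratio between 0.926 and 0.982, with the 299 peaks held fixed. These peaks were chosen on the average of both histories in the same libraries, which draws the ratio towards 1. The interval does not cover this choice. In peaks chosen in batches 1 and 2 and tested in batches 3 and 4, the ratio was 0.705 (0.380 to 1.03, fry adjusted p = 0.332), and with the order of batches reversed it was 1.00 (0.379 to 1.63, fry adjusted p = 0.849, 100 peaks of which 1 was called). Both intervals include a smaller and an equal response after chronic restraint. By batch the acute change of the set was 0.34, 0.43, 0.39 and 0.43. None of the 17 gene lists differed between the histories (camera, smallest adjusted p = 0.771).

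**Figure D5:**
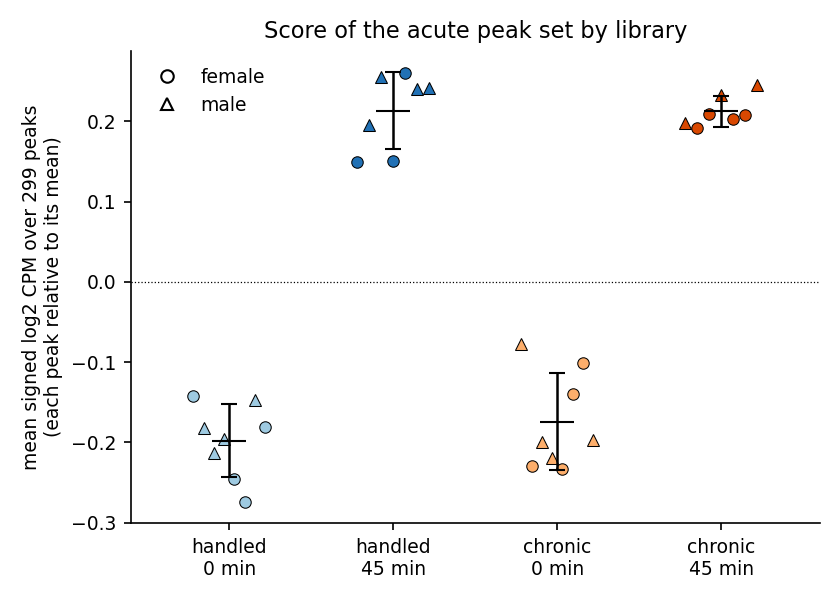
Mean signed log2 CPM over the 299 acute peaks, each relative to its own mean, for each library by group; circles are females, triangles males, and bars give the mean and SD. The peaks were selected on the contrast of 45 min with 0 min, so the separation of times is expected; the means at 45 min are 0.21 in both histories, and those at 0 min −0.20 in handled and −0.17 in chronically restrained mice.

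Before the acute restraint, chronically restrained and handled mice showed no called difference in accessibility. The smallest p values belonged to peaks within Hip1, an endocytic adaptor (−0.72 ± 0.16), within Shc3, a neuronal signalling adaptor (−0.75 ± 0.17), and within Fkbp5 (chromosome 17, 28419585 to 28420016, 0.67 ± 0.15, unadjusted p = 3.1e-05), none of which passed over all peaks. The Fkbp5 peak was the 1 peak of the glucocorticoid receptor targets that was higher when adjusted over the list alone. As a list these targets had a median of −0.015 (camera adjusted p = 0.858), and the 299 acute peaks had a mean signed change of 0.023 (fry adjusted p = 0.871). By edgeR and by DESeq2 0 peaks passed, 11817 had an unadjusted p under 0.05 against 12857 expected, and the smallest adjusted p was 0.997. In males alone 4 peaks passed. Within batches 1, 2 and 3 alone the counts were 8, 3 and 11, of which the 3 in batch 2 were higher after chronic restraint and the others lower. Batch 4 held 6 libraries, with 1 library per history at 45 min and animal 45 among its handled mice at 0 min, so its count is not read.

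At 45 min the histories again showed no called difference. The named peaks were near Otol1 (−0.77 ± 0.16), within Irf2, an interferon regulatory factor (0.76 ± 0.18), and within Wipi2, an autophagy protein (0.68 ± 0.16), and none passed. Immediate early genes had a median of −0.027 (camera adjusted p = 0.278) and glutamate receptors a median of 0.031 (adjusted p = 0.238). By edgeR and by DESeq2 0 peaks passed, and 9723 had an unadjusted p under 0.05. Within single batches the counts were 1, 11, 0 and 0, the last with 1 library per history.

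Averaged over both times, the oligodendrocyte marker list was the only list that passed. Its peaks, which include those of the myelin genes Mbp and Mog, had a median log2 change of −0.034 after chronic restraint and 29.7% were positive (camera adjusted p = 0.0425, adjusted p = 0.340 with an estimated correlation). The call ended with total count scaling, with a flank of 50 kb and over gene-end peaks only, with an adjusted p from 0.0361 to 0.852 over all settings. None of its 138 peaks passed alone, over all peaks or adjusted over the list alone. Lists of precursor, excitatory and microglial markers had medians of −0.029, −0.033 and −0.020 and did not pass. The named peaks lay over Faah, which encodes the enzyme that breaks down anandamide (0.23 ± 0.045), near Shisa9, an auxiliary subunit gene of AMPA receptors (−0.57 ± 0.11), and within Hecw2, a ubiquitin ligase (−0.56 ± 0.11), with adjusted p of 0.278 for each. By edgeR 0 peaks passed, DESeq2 called 1, over Faah, and 13995 had an unadjusted p under 0.05 against 12857 expected. In simulated counts the same test recovered 91.0% of peaks changed 1.5-fold and 41.8% of peaks changed 1.25-fold. Smaller changes, and variation shared between peaks, were not simulated. Within single batches the counts were 1, 0, 0 and 0.

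Between the sexes, a few autosomal peaks differed. A peak within Cpeb4, a regulator of mRNA polyadenylation and translation (chromosome 11, 31922650 to 31923128), had 1.07 ± 0.24 CPM in females and 2.79 ± 0.43 CPM in males (SD, n = 15 each; log2 change −1.36 ± 0.094, adjusted p = 4.4e-20), with no overlap between the sexes. A peak 131681 bp from Adra2a, the alpha-2A adrenergic receptor gene, was higher in females (0.44 ± 0.086, adjusted p = 0.0082), as was a peak over an end of Slc22a29, an organic anion transporter gene (0.47 ± 0.086, adjusted p = 0.0024). A peak near Tmem161b was lower in females (−0.57 ± 0.12, adjusted p = 0.0418). These 4 of 255089 autosomal peaks passed (edgeR), against 8 by DESeq2 and 8 without animal 45.

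The acute response differed between sexes at a single peak, between genes on the distal Y chromosome near Gm52481 (90730971 to 90731195, log2 difference 1.36 ± 0.23, adjusted p = 0.0291, edgeR; 1 call by DESeq2). Its mean CPM in handled females was 1.06 ± 0.22 (SD, n = 4) at 0 min and 1.68 ± 0.48 (n = 3) at 45 min, and in handled males 1.49 ± 0.71 (n = 4) and 0.942 ± 0.26 (n = 4). In chronically restrained females it was 0.990 ± 0.29 (n = 4) and 1.45 ± 0.24 (n = 4), and in chronically restrained males 1.58 ± 0.31 (n = 4) and 0.877 ± 0.26 (n = 3). Single libraries had a high share of counts in distal Y peaks. These were animal 39, 1 of the 3 handled females at 45 min (0.0540%, Wilson 0.0533 to 0.0547), and animal 49, a handled male at 0 min (0.0546%, 0.0539 to 0.0554), which run the way of this difference, and animals 57 (0.0523%, 0.0515 to 0.0531) and 34 (0.0558%, 0.0551 to 0.0566), females at 0 min, which run against it. The lowest share, 0.0034% (0.0032 to 0.0036), was that of animal 46, a chronically restrained female at 0 min, which runs the way of the difference. At the called peak the lowest female value was 0.648 CPM. Females carry no Y chromosome, so their counts there must come from other sequence placed on it. Where these counts arose was not tested, so the call does not show a change at the Y chromosome itself. This peak was named after its values were seen, as the only call. The call ended with library pool in place of batch, without a batch term, and without batch 1, 2 or 3 (0 calls each). No peak was called for a difference in the effect of chronic restraint between sexes (edgeR and DESeq2, 0 calls each). By edgeR 23833 peaks had an unadjusted p under 0.05 against 12857 expected, and the smallest adjusted p was 0.245. This comparison was not simulated, so the share of true differences it would recover is unknown, and smaller differences stay open.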

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

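The tests of other cell types and of the split with the highest count, and every fit without animal 45, were chosen only after the results were seen. Single libraries were compared with the rest of their group of 7 or 8 on 32 measures. A library stood apart where its gap to the nearest other library took up more of the group's range than Dixon's 95% limit allows, and that share of the range is given below. Of 128 such tests 16 passed, where about 6 are expected, since chance alone passes about 1 in 20 groups.

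For the acute gain at the glucocorticoid receptor target peaks, the signal-to-noise of the libraries was weighed with the share of counts in the most covered 1% of peaks as a covariate. All 19 called peaks of the list remained called and higher, among 38 higher and 2 lower calls in the list. All 299 acute peaks also remained called. The share was 20.6% at 45 min and 20.5% at 0 min (permutation test, unadjusted p = 0.427). Adjusting for it could thus hardly have ended these calls, and the fit does not decide on signal-to-noise. The lowest mean change of the list in any of the 4 batches was 0.048, above 0, which argues against a batch. More cells of another type at 45 min would raise their own markers, and the highest upper 95% bound of the mean change over 8 lists of other cell types or regions was 0.052, for oligodendrocyte markers, against a mean of 0.086 (0.064 to 0.11) for the targets. The oligodendrocyte members moved apart, with a median of 0.16 over the peaks of Mobp and −0.21 over those of Ermn, and 7 peaks higher and 2 lower when adjusted over the list alone, where more cells would raise them alike. Excitatory neuron markers, not among the 8 lists, had a mean change of −0.036 (−0.068 to −0.0034), the direction that a smaller share of these cells would give. Peaks near a marker need not be specific to its cell type, so these means cannot settle a change in cell shares. GC content was not tested and stays open. Signal-to-noise, a change in cell shares and a response to the acute restraint itself also stay open, so no source of the gain is singled out.

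The library of animal 45, in the handled group at 0 min, stood apart on 6 measures. Its share of counts at gene ends was 42.1% (95% Wilson interval 42.13 to 42.16), against 37.7% to 39.6% in the others (gap 0.566 of the range). Its TMM factor was 0.875 against 0.987 to 1.03 (0.717), and its score on the first principal component, which held 14.6% of the variance, was −224 against −25.6 to 57.8 (0.704). Mean levels of lists are given relative to all libraries, on the log2 scale. For glucocorticoid receptor targets its level was −0.13 against −0.051 to −0.0027 (0.622). For chromatin enzymes it was −0.089 against −0.022 to 0.028 (0.575), and for inhibitory neuron markers 0.13 against −0.072 to −0.00020 (0.635).

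For this library a wrong time label, a general trend of counts towards gene ends, and its part in the splits of the handled mice were weighed. Its mean signed level over the 681 acute peaks called without it was −0.088. This lay below the 14 libraries at 45 min (0.12 to 0.23) and within the other 15 at 0 min (−0.22 to −0.024). It argues against a swapped time, but the score joins 2 parts. Over the 299 peaks called with all libraries, its level at those that rose was 0.025. That was below the libraries at 45 min (lowest 0.110) but above the other handled ones at 0 min (highest −0.105). At those that fell it was 0.78, above every other library (highest 0.39). The low signed level thus rests largely on the peaks that fell, in a library that stood apart in other ways, which limits this evidence. Across the other 29 libraries the first component fell with the gene-end share (Pearson r −0.623, permutation p = 0.00033; Spearman rho −0.643, p = 0.00025; r −0.519 without the 2 farthest libraries; −0.88, −0.50, −0.85 and 0.14 in batches 1 to 4), but that relation predicts −104 for animal 45, where −224 was observed with a residual SD of 27.1, so a stronger form of this trend stays open and no biological explanation was tested. Other splits of the handled mice called up to 5887 peaks, and the split with 5887, which moves animal 45 to 45 min, called 1 without that library. Another split called 385 with all libraries and still 241 without animal 45, where the real split called 108. This argues against this library as the whole source, and what else lies behind that split was not traced.

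Chance groupings were compared with the real one in 40 splits per comparison, the real one included. For the acute effect in handled mice 3 of 40 splits reached the real count (real 28, highest other 5887), so chance could not be excluded there. In chronically restrained mice (real 7, highest other 1) and for the averaged acute effect (real 299, highest other 1) only the real split did, 1 of 40. That is the lowest share that 40 splits can give. For the averaged effect it argues against chance without excluding it. In chronically restrained mice the calls ended without batch 2 and in females, so chance stays open there. For the acute effect by sex the real split was also the only 1 of 40 (real 1, highest other 0). This rests on a single peak whose call other settings ended, so it is not read as arguing against chance. For the autosomal sex difference 3 of 40 splits reached it (real 4, highest other 270), so chance could not be excluded for the count. What lies behind the split with 270 calls was not traced. The count does not bear on the Cpeb4 peak, with an adjusted p of 4.4e-20 (edgeR). There 15 females (at most 1.70 CPM) and 15 males (at least 2.15 CPM) did not overlap. With a real count of 0, all 40 of 40 splits reached it for chronic restraint at 0 min (highest other 1), at 45 min (1) and averaged (1), for the interaction (18) and for the chronic effect by sex (0).

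The other libraries that stood apart are given as values. Animal 66, chronically restrained at 45 min, had 39.9% of its counts at gene ends (Wilson 39.93 to 39.96) against 38.2% to 38.9% (0.599), 21.3% in the most covered 1% of peaks (21.24 to 21.27) against 20.3% to 20.7% (0.602), a TMM factor of 0.977 against 1.00 to 1.02 (0.659) and a microglia marker level of −0.076 against −0.011 to 0.037 (0.572). Animal 63, chronically restrained at 0 min, scored 71.7 on the first component (0.532) and 96.4 on the second (0.657). Animal 18, handled at 45 min, scored −86.3 on the second component (0.751). Animal 39, handled at 45 min, had 0.0540% of its counts in distal Y chromosome peaks (Wilson 0.0533 to 0.0547) against 0.0223% to 0.0350% (0.598). Animal 51, chronically restrained at 0 min, had an astrocyte marker level of −0.090 against −0.017 to 0.040 (0.556). Animal 8, handled at 0 min, had 2.63 CPM at the Ttyh1 peak against 1.09 to 1.82 (0.529). The intervals cover counting error only. The acute response differed between sexes at the distal Y peak near Gm52481, by 1.36 on the log2 scale (edgeR, adjusted p = 0.0291), a test of the difference itself. Females also had counts at this peak, so it cannot reflect the Y chromosome alone.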

How the results depend on the processing

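The setting without animal 45 was chosen only after the results were seen; all other settings were planned. Counts of called peaks are given, with higher and lower peaks in brackets where they matter, for settings that moved a count by over 1.5 times. For the acute effect in handled mice (28), total count scaling gave 64, loess offsets 51, DESeq2 57, surrogate variables 312, the top-peak share 375 (92 higher, 283 lower), without batch 1 16, without batch 2 0, without batch 3 0, without batch 4 53, females 0, males 0, without animal 45 108, and an adjusted p under 0.1 gave 51. In chronically restrained mice (7) the same settings gave 26, 21, 24, 119, 55, 18, 0, 1, 17, 0, 1, 47 and 19, and library pool gave 4. For the averaged acute effect (299), total count scaling gave 525, loess offsets 460, surrogate variables 1109, the top-peak share 1763 (498 higher, 1265 lower), without batch 2 40, without batch 3 140, females 20, males 105, without animal 45 681, and an adjusted p under 0.1 gave 538; of the 299 peaks 298, 298, 282, 299, 40, 112, 19, 71, 299 and 299 remained called. For chronic restraint at 0 min (0) males gave 4. Averaged over times (0), loess offsets, DESeq2, library pool and surrogate variables gave 1 each (the Faah peak but for library pool), the top-peak share 3 and males 2. At 45 min, for the interaction and for the chronic effect by sex, each of these settings gave a count of 0, while fits within single batches called 1, 11, 0 and 0 peaks at 45 min and 9, 11, 1 and 15 for the interaction, with 1 library per history at 45 min in batch 4. For sex (4), DESeq2 gave 8, library pool 1, surrogate variables 27, without batch 2 1, without batch 3 8, without batch 4 9, without animal 45 8, and an adjusted p under 0.1 gave 9. In batch 2 each library pool held 1 sex alone, so with library pool as a covariate that batch did not inform the sex comparison. For the acute effect by sex (1), library pool, no batch term, without batch 1, 2 or 3, and autosomes only gave 0. Fits without a batch or in 1 sex held fewer libraries, but this alone does not account for their counts. Batches 1, 2 and 3 held 8 libraries each. For the averaged acute effect the count was 40 without batch 2 and 140 without batch 3, and without batch 1 it moved by no more than 1.5 times. The cause of these and of the other changes was not tested. Of 112 results for named peaks 52 were called; all 52 kept their direction in each setting run and 9 kept their call in each. The peaks of glucocorticoid receptor targets that rose numbered 5 to 41 over the settings, and 2 fell with the top-peak share as a covariate and none in the others. Lists that passed camera numbered 2 over gene-end peaks only for the acute effect in handled mice (1 in the test reported), 2 for chronic restraint at 45 min (0), and 3 averaged over times (1), where a flank of 50 kb gave 0, the estimated correlation 0, total count scaling 0, and without animal 45 2. The ratio of the acute set in chronically restrained to handled mice (0.950) was 0.926 to 0.982 without each library in turn, 0.932 for the 1000 peaks with the smallest p, 0.946 with total counts, 0.958 in females, 0.942 in males and 0.705 in batches 3 and 4; it reversed, without a call, to 1.00 for 100 peaks chosen in batches 3 and 4 (1 of them called) and tested in batches 1 and 2; the cause was not tested. Ratios without single libraries, with total counts and by sex used the same 299 peaks, chosen with all 30 libraries. Correction for GC content and motif sets were not run. With 7 or 8 libraries per group and a median of 58.97 counts per peak, at most 41.8% of simulated changes of 1.25-fold were recovered in any of the 7 stress comparisons.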

Other observations

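The test of lists against other gene-end peaks alone was chosen after the planned test of gene-end peaks had been seen. Several genes held a pair of peaks that changed together at 45 min against 0 min, averaged over both histories (edgeR, 14 against 16 libraries). Both peaks fell within Pcdh15, a protocadherin (−0.73 ± 0.12 and −0.51 ± 0.11), within Cdh12, a cadherin of neurons (−0.40 ± 0.084 and −0.80 ± 0.17), within Syne1, which encodes a protein of the nuclear envelope (−0.30 ± 0.066 and −0.24 ± 0.056), within Frmpd2 (−0.28 ± 0.058 and −0.22 ± 0.052), and near Galc, the gene of a lysosomal galactosidase of myelin lipids (−0.36 ± 0.077 and −0.33 ± 0.074). Both rose within Htra1, a secreted serine protease (0.24 ± 0.045 and 0.25 ± 0.059), within Atp2c2, a calcium and manganese pump (0.24 ± 0.051 and 0.34 ± 0.072), and near Ptpn1, a tyrosine phosphatase gene (0.49 ± 0.070 and 0.31 ± 0.069). At or near Adamts5, Jarid2, Kif6 and Prkar2a 1 peak rose and 1 fell. Each of these peaks had an adjusted p under 0.05 and they were chosen after their values were seen. The peaks that rose had a median width of 1182 bp and 52.7% lay within genes, and those that fell had a median width of 674 bp and 45.0% lay within genes, against 561 bp and 69.9% of all tested peaks.

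A hypothesis is that, at 45 min, the ends of immediate early genes may be less accessible in chronically restrained than in handled mice. Over the 89 gene-end peaks of that list the median log2 change was −0.058, and 73 were lower. A general loss at gene ends was the explanation tested against it. The median of all gene ends was −0.016, and against the other gene-end peaks alone camera gave an adjusted p of 0.0022, which argues against a general loss, but the adjusted p was 0.988 with an estimated correlation. That correlation was 0.13 where the preset was 0.01, so these peaks vary together between libraries far more than the preset test assumes, and the question stays open. The mean difference of the list was −0.032, −0.080, −0.032 and −0.054 in batches 1 to 4 at 45 min, and −0.036, 0.021, −0.047 and −0.025 at 0 min. Without animal 45 the adjusted p was 9.8e-04.

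Other lists were tested over gene-end peaks in the same way. At 45 min the circadian clock list was lower after chronic restraint (median −0.049, 29 of 34 peaks lower, adjusted p = 0.0052, adjusted p = 0.988 with an estimated correlation), and choroid plexus markers were higher (1 of 10 peaks lower, median 0.12, adjusted p = 0.0314, adjusted p = 0.142 with an estimated correlation). Averaged over times, immediate early genes (median −0.049, adjusted p = 0.0023) and the clock list (median −0.041, adjusted p = 0.0158) were lower, with an adjusted p of 0.761 for both with an estimated correlation, and without animal 45 the clock list did not pass (0.0734) while glutamate receptors did (median 0.015 with all libraries, adjusted p = 0.0410, adjusted p = 0.761 with an estimated correlation and all libraries). Before acute restraint, inhibitory neuron markers were higher after chronic restraint (median 0.083, adjusted p = 0.0192, adjusted p = 0.0616 with an estimated correlation), and did not pass without animal 45 (0.358), while glutamate receptors passed only without it (adjusted p = 0.0388, adjusted p = 0.739 with an estimated correlation and all libraries). For the averaged acute effect the gene ends of glucocorticoid receptor targets were higher (median 0.094, 11 of 58 lower, adjusted p = 3.1e-20, adjusted p = 0.0108 with an estimated correlation).

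In peaks chosen for the acute effect in batches 1 and 2, and tested in batches 3 and 4, the mean signed acute change was 0.29 and 89.5% of 152 peaks changed in the same direction (fry adjusted p = 1.4e-05). In the reverse order, with 100 peaks of which 1 was called, it was 0.32, and 90% changed in the same direction (adjusted p = 1.5e-05).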
